A study of Homo sapiens with 8 samples.

How the data were processed

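H3K4me2 was measured in 4 immunoprecipitated libraries of LNCaP cells, 2 labelled DMSO and 2 labelled bizine; the 4 input samples of the series were not analysed here. Per the submitters' processing notes, the tools were CASAVA 1.8.2, BWA and MACS2 and the build was hg19; the versions of BWA and MACS2 are not given in the sources used here. Each deposited list gives the position of every peak, a name and a score, and was called for 1 library. The score deposited by the authors lies on the −log10 scale of a q-value, starting just above 1.30 in each list, as MACS2 writes it. It is the authors' value for that peak. It was used to rank peaks within a list and, as a median per segment or chromosome, in correlations with the difference in share. Depth was unknown, and a list called from more reads tends to be longer and its peaks wider, so counts, widths and coverage are not corrected for depth.

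Groups were taken from the sample titles. Within the lists, the peak names of DMSO 2 and bizine 2 read as if these 2 libraries were exchanged, so groups as the peak names read were run as an alternative, chosen after seeing the data. Peaks on chromosomes 1 to 22, X and Y were used, which was every peak. Covered bases and merged regions were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15; a library was present in a merged region with at least 1 bp of a peak. The interval functions were checked against direct counting on 50 random datasets, with 0 mismatches. Group means of single values were compared with exact two-sided permutation tests in scipy 1.17.1.

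For loci, the percent of each 5 kb bin covered by peaks was tested with limma 3.58.1 in R 4.3.3 (trend and robust), over bins with a mean of at least 5% covered, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. No scaling between libraries was applied. Named bins are the 3 with the largest mean difference in each direction, and named one-sided regions the 3 widest in each direction. On simulated bins the fit made 8 false calls among 83965 bins with 200 changed.

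The comparisons over chromosomes and 5 Mb segments (at least 200 peaks over the 4 lists) were added after seeing the data. They used limma with a trend and without the robust option on the log2 share of a library's peaks. That fit was itself chosen after the calls under other fits had been seen, because the fit with trend and robust made many false calls on simulated chromosomes. On 100 unchanged simulated datasets the fit used made 12 false calls over chromosomes, in 10 of the datasets, against 37 with trend and robust and 27 without trend. Over segments it made 4 against 3 and 22, so it was not the fit with the fewest there. On the deposited lists, trend and robust called 12 chromosomes and 75 segments, and the fit without trend called 8 and 59. The fit used recovered 97 of 100 chromosomes changed by 0.25 on the log2 scale and 265 of 300 segments changed by 0.5. Apart from these changes the simulated libraries had the same expected shares, with independent noise and no shift of shares with list length. Changes were placed only where the share was below the median, and most chromosomes called in the lists differed by less than 0.25. The rates may thus not hold for the lists.

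The same number of top-scoring peaks means the 113916 highest scores of each list, the length of the shortest. Many peaks share a score: 4745 peaks of bizine 2 and 3448 of DMSO 1 had the lowest score kept. Ties were first broken by width, which favours wide peaks in the lists that are shortened. They were changed to a seeded random order after those results had been seen, and the order by width and 10 other random orders were run beside it. Shortening also removes mainly weak and narrow peaks from the longer lists, so it does not equalize depth.

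Other alternatives were the top-scoring 50% of each list, joining peaks within 500 bp, presence over at least 50% of a region, other bin sizes, quantile normalization, no filter, each library left out and a replicate block. These, the tests, the bins and the rule for named items were set before the data were examined, unless said otherwise. Windows at gene 5' ends, gene bodies, gene lists and the share of bases near genes were planned but not run, since a gene annotation of hg19 was not used here, and no region is given a gene name.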

Results

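Dimethylated lysine 4 of histone H3 (H3K4me2), a mark of promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in LNCaP cells, an androgen-sensitive line derived from a prostate cancer metastasis. Cells were kept for 48 h in serum-free medium with vehicle (DMSO) or with 10 µM bizine, a phenelzine analog that inhibits the histone demethylase LSD1. LSD1 (KDM1A) removes methyl groups from mono- and dimethylated lysine 4 of histone H3. Each treatment had 2 immunoprecipitated libraries, and a peak list of each was analysed. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The libraries labelled DMSO held 130038 and 113916 peaks, and those labelled bizine held 147397 and 162099. The number of reads behind each list is unknown. The names of the peaks in 2 lists went against the labels. The list of the second DMSO library carried the code P952, like the code P951 in the list of the first bizine library. The list of the second bizine library carried the name DMSO2. The input named beside each carried the same code. That the code stands for bizine is inferred from the first bizine library. Groups follow the labels throughout, and every direction given between groups depends on them.

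The first comparison asked whether LSD1 inhibition changed the extent of H3K4me2 across the genome. The libraries labelled bizine had more peaks and more of the genome under peaks. The peak count averaged 154748 ± 10396 (SD, n = 2) in the libraries labelled bizine and 121977 ± 11400 (SD, n = 2) in those labelled DMSO, a ratio of 1.27. Covered length was 102 and 94.0 Mb in the libraries labelled bizine and 74.8 and 61.8 Mb in those labelled DMSO, a ratio of means of 1.43, which was 1.27 with the same number of top-scoring peaks in each list. Broad peaks of at least 2 kb numbered 4880 and 2842 against 2223 and 1443. The mean peak width was 691 and 580 bp against 575 and 543 bp, and the difference in means of 76.6 bp was 21.0 bp without bizine 1, 132 bp without bizine 2 and 158 bp with equal numbers of top-scoring peaks. Wider peaks scored higher in each list (Spearman's rho 0.546 to 0.627). The cut by score thus drops mainly narrow peaks from the longer lists and none from DMSO 2, and raises the 158 bp partly by construction. Lists of equal number differ in covered length only through mean width. The ratio of 1.27 in covered length with equal numbers is therefore the same result as the 158 bp, with the same limit. The groups did not overlap in any of these measures, and the exact two-sided permutation test gave p = 0.333 for each, the smallest value that 2 libraries against 2 allow. With the groups taken as the peak names read, the difference in peak count was -15412 and that in covered length -2.56 Mb.

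**Figure D1:**
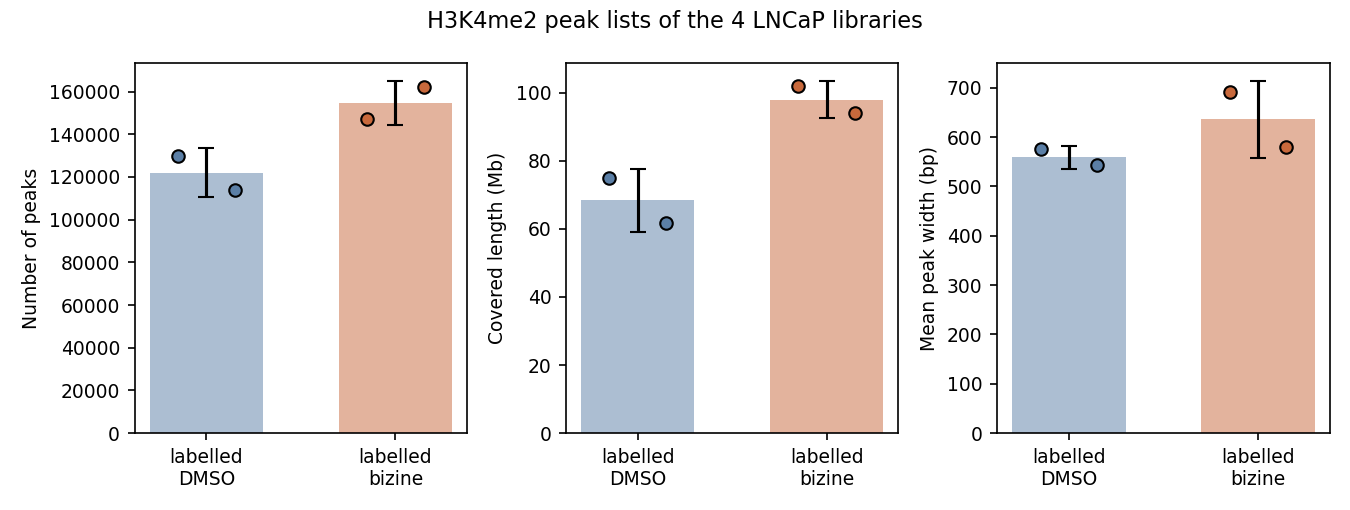
Number of peaks, covered length (Mb) and mean peak width (bp) of the H3K4me2 lists labelled DMSO and bizine. Points are libraries, bars the group means and error bars the SD (n = 2); covered length was 74.8 and 61.8 Mb in the libraries labelled DMSO and 102 and 94.0 Mb in those labelled bizine.

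The same question was then put to regions that carried a peak in every library. Merging all lists gave 198120 regions, of which 60565 (30.6%) had a peak in all 4 libraries. Within these shared regions, peaks covered a mean of 1176 and 1065 bp per region in the libraries labelled bizine and 960 and 856 bp in those labelled DMSO, a ratio of means of 1.23. Of the shared regions, 35.7% were covered further in both libraries labelled bizine than in both labelled DMSO and 6.77% showed the reverse. If all orders of the 4 libraries were equally likely, each would be 16.7%. The split by replicate number gave 22.1% wider in both libraries numbered 1 and 8.50% in both numbered 2. By peak name the values were 13.8 and 12.8%. An offset common to all regions of a library moves these percentages, so they do not show an excess region by region. The median ratio of covered bases was 1.22. It was 1.20 with the 113916 top-scoring peaks of each list, over the 49993 regions that those shortened lists shared. With all peaks, the other splits of the 4 libraries gave median ratios of 1.01 by peak name and 0.905 by replicate number. The widest shared region (hg19, chromosome 21, 17693022 to 17714477) was covered over 19128 and 18919 bp in the libraries labelled DMSO and 19692 and 17548 bp in those labelled bizine, which did not separate the groups. A region of 17662 bp on chromosome 22 (46468904 to 46486565) was covered over 14060 and 14113 bp against 16320 and 12890 bp. The next widest, on chromosome 21 (17714724 to 17731785), separated the groups, with 12440 and 11704 bp in the libraries labelled DMSO and 14079 and 13086 bp in those labelled bizine. These 3 regions were chosen after their values were seen.

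The next comparison asked which regions carried the mark under 1 treatment alone. Regions with a peak in both libraries labelled bizine and neither labelled DMSO numbered 13327, and those with the reverse pattern numbered 1827. The widest bizine-only region lay on chromosome 6 (26217183 to 26219403) and was covered over 2221 and 831 bp in the 2 libraries labelled bizine. The next widest lay on chromosome 1 (224325564 to 224327570), with 2007 and 633 bp, and on chromosome 18 (40720715 to 40722680), with 1297 and 1516 bp. The widest DMSO-only regions lay on chromosome 21 (30713636 to 30715130), chromosome 17 (20073558 to 20074888) and chromosome 1 (156462579 to 156463819), covered over 668 and 921 bp, 443 and 1124 bp, and 576 and 1021 bp. One-sided regions held weaker peaks than shared regions. For each region the score percentile of its best peak within each list was averaged over the lists with a peak. The median over regions was 36.8 for bizine-only and 32.7 for DMSO-only regions, against 68.2 for shared regions. Regions with a peak in just 1 library of each label gave 32.3 to 33.7, so low scores were not particular to one-sided regions. Shared regions were wider (median 1343 bp against 523 and 426 bp) and can hold several peaks, which can raise their best score. With the same number of top-scoring peaks in each list the counts were 6810 and 3618. By comparison, at that number the split by peak name gave 3800 and 4266 one-sided regions and the split by replicate number gave 5178 and 3260.

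**Figure D2:**
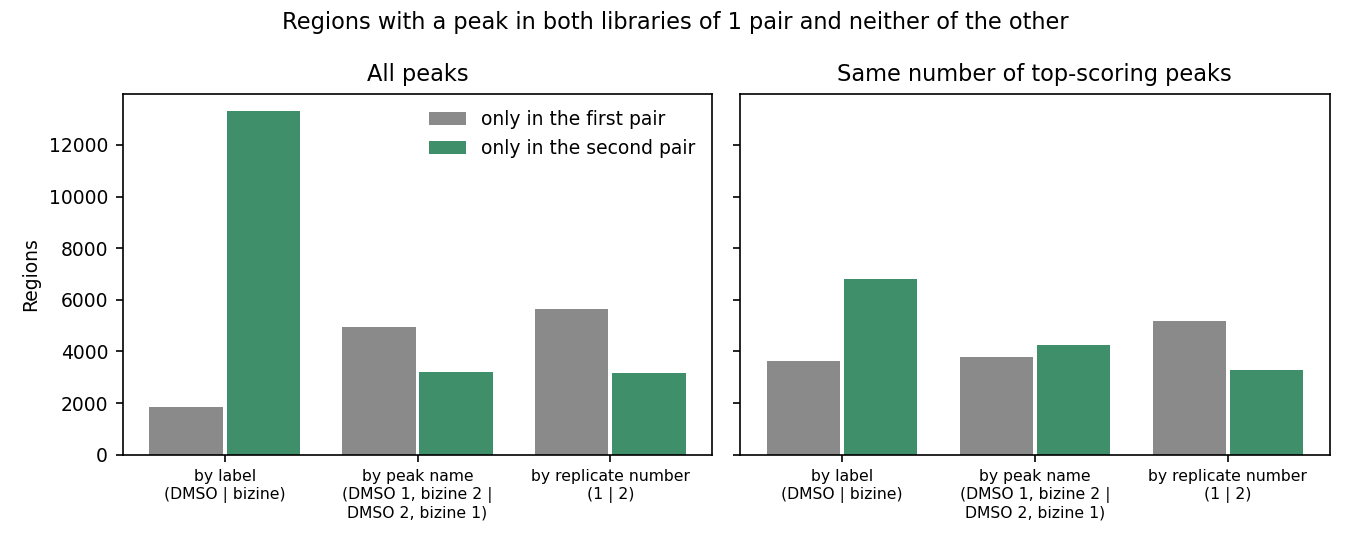
Numbers of regions with a peak in both libraries of 1 pair and in neither of the other pair, for the 3 ways to split 4 libraries into pairs, with all peaks (left) and with the same number of top-scoring peaks (right). By label, 13327 regions were bizine-only and 1827 DMSO-only with all peaks, and 6810 and 3618 with equal numbers.

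The base overlap of the lists set pairs within a group against pairs across groups. The Jaccard index, the shared bases as a percent of all bases covered by either list, was 40.0% for the pair labelled DMSO and 45.4% for the pair labelled bizine. The 4 pairs across the labels gave 43.2, 39.7, 39.0 and 36.6%. The DMSO pair thus overlapped less than DMSO 1 and bizine 1 did, and the mean of 42.7% ± 3.86 (SD, 2 pairs) within groups differed from that of 39.6% ± 2.72 (SD, 4 pairs) across groups by about the spread between pairs.

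Coverage of single loci was compared in bins of 5 kb, of which 83965 passed the filter. No bin passed an adjusted p of 0.05 in limma (lowest 0.259). At an unadjusted p under 0.05, 12083 bins were higher and 303 lower in the libraries labelled bizine, where chance gives 4198 in all. After quantile normalization these counts were 3507 and 2626. The bin with the largest positive difference in mean coverage lay on chromosome 10 (25545001 to 25550000), with 29.0 and 0% covered in the libraries labelled DMSO and 67.3 and 66.0% in those labelled bizine. On chromosome 16 (69230001 to 69235000) the values were 12.4 and 0% against 40.5 and 72.3%, and on chromosome 1 (161410001 to 161415000) 0 and 0% against 48.9 and 51.2%. The bins with the largest negative differences lay on chromosome 5 (145845001 to 145850000), with 46.1 and 40.9% against 6.84 and 16.7%, on chromosome 22 (46500001 to 46505000), with 60.6 and 47.4% against 25.0 and 19.7%, and on chromosome 19 (39620001 to 39625000), with 44.6 and 46.5% against 24.9 and 10.4%. In bins of 10 kb, 1 bin passed in limma: chromosome 1, 161410001 to 161420000, with 1.94 and 2.35% against 47.2 and 48.9% (difference 45.9 ± 4.39 percentage points, SE; adjusted p = 0.00726). On simulated data limma recovered 25 of 100 bins raised by 30 percentage points and 100 of 100 raised by 60. The simulated libraries drew independent residuals pooled over bins of similar coverage, with no offset between libraries. In the lists the median difference over bins was 5.27 points, so these rates may not hold for them.

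The distribution of peaks over chromosomes was examined after the lists had been seen, because the share on chromosome X stood out. Chromosome X held 2.25 and 2.16% of the peaks in the libraries labelled bizine and 1.55 and 1.498% in those labelled DMSO, a log2 difference of 0.53 ± 0.03 (SE). The share was also higher on chromosome Y (0.330 and 0.331% against 0.208 and 0.180%, log2 0.77 ± 0.14), chromosome 13 (2.62 and 2.61% against 2.37 and 2.33%, log2 0.15 ± 0.02) and chromosome 2 (7.68 and 7.60% against 7.03 and 7.01%, log2 0.12 ± 0.01). Chromosomes 1, 7, 9, 11, 14, 15, 16 and 17 had lower shares, of which chromosome 1 differed most (8.95 and 9.10% against 9.49 and 9.46%). These 12 of 24 chromosomes passed limma at an adjusted p of 0.05. The shares of a list add to a fixed total, so higher shares on some chromosomes lower those of others. No chromosome had a lower mean peak count in the libraries labelled bizine. The smallest ratio of mean counts was 1.21, on chromosome 1 (13197 and 14746 peaks against 12335 and 10782 in the libraries labelled DMSO). The lower shares thus show no loss of peaks, and the counts are not corrected for depth. The counts of passing chromosomes depended on single libraries: 6 without DMSO 1, 5 without DMSO 2, 4 without bizine 1 and 7 without bizine 2. With equal numbers of top-scoring peaks, 5 chromosomes were higher and 2 lower. None of the 8 chromosomes with lower shares passed as lower in that fit: chromosome 1 lay at -0.02 (adjusted p = 0.100), chromosome 16 turned to 0.03 (adjusted p = 0.203) and chromosome 17 turned to 0.04 and passed as higher (adjusted p = 0.0493), while the lower calls were chromosomes 3 and 4. That count changed from 2 to 7 over 10 other random orders of peaks with tied scores, among which chromosomes X (log2 0.24) and 19 (log2 0.12) passed in all 10 orders, chromosome 13 in 7, chromosome 4 in 3, chromosome 17 in 2, chromosomes 2 and 3 in 1 each and chromosome Y in 0. Among the 20000 top-scoring peaks of each list the share of chromosome X was lower in the libraries labelled bizine, 0.280 and 0.335% against 0.535 and 0.510% (log2 -0.77). Shares were also lower there, with the groups apart, on chromosomes 2 (log2 -0.11), 11 (log2 -0.05), 13 (log2 -0.19), 21 (log2 -0.13) and 22 (log2 -0.30). They were higher there, with the groups apart, on chromosomes 1, 3, 5, 7, 8, 12, 15 and 18, by at most log2 0.12 (chromosome 18). Among the top 50000 the values were 0.08 on chromosome X, with overlapping groups, 0.07 on chromosome 2 and 0.09 on chromosome 13. Top-scoring sets come from lists of different length, so these values describe the lists and show no change in the mark.

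**Figure D3:**
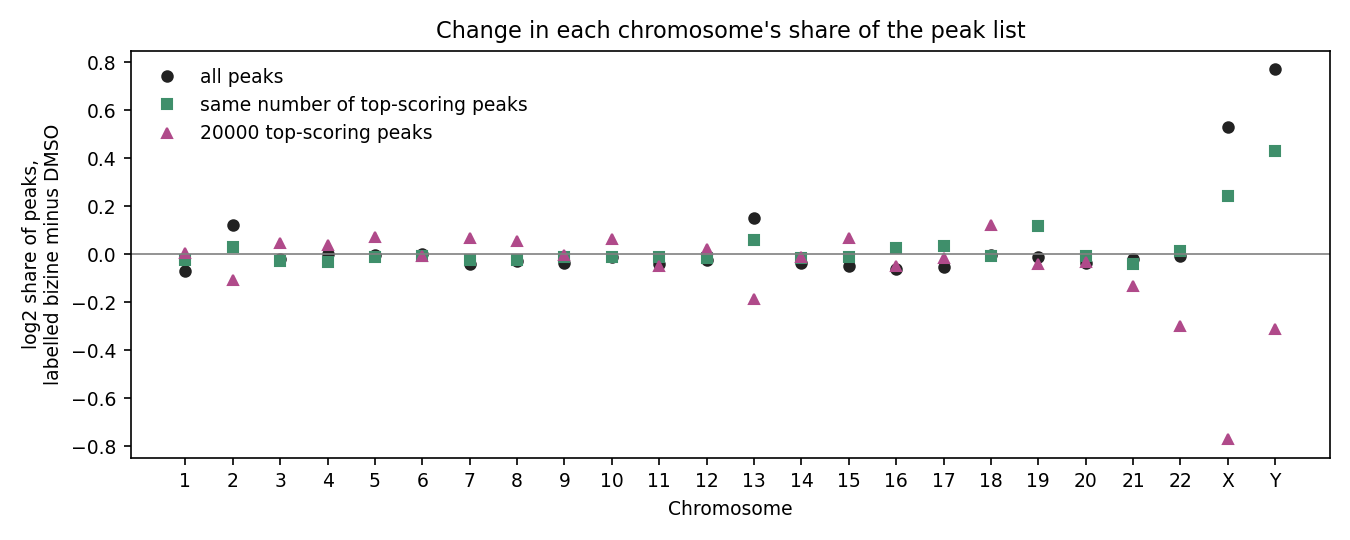
Difference in the mean log2 share of peaks on each chromosome, libraries labelled bizine minus those labelled DMSO (n = 2 each), with all peaks, the same number of top-scoring peaks and the 20000 top-scoring peaks. Chromosome X lay at 0.53 with all peaks, 0.24 with equal numbers and -0.77 among the top-scoring peaks.

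Segments of 5 Mb, also examined after the lists had been seen, located these differences. Of 580 segments, 59 had a higher and 13 a lower share in the libraries labelled bizine at an adjusted p of 0.05 in limma. The higher segments included 20 of 23 on chromosome X, 4 of 4 on chromosome Y, 17 of 48 on chromosome 2 and 5 of 17 on chromosome 13. On chromosome X the segment from 95000001 to 100000000 held 37 and 27 peaks in the libraries labelled DMSO and 86 and 92 in those labelled bizine (log2 difference in share 1.15 ± 0.13, SE). On chromosome 2, each segment from 40000001 to 75000000 was among those with a higher share, with 98 and 74 peaks against 165 and 160 in the first (log2 0.59 ± 0.10). On chromosome 13 the segment from 90000001 to 95000000 held 170 and 125 against 237 and 273 peaks (log2 0.46 ± 0.07). The number of passing segments was 27 without bizine 1 and 37 without bizine 2. With equal numbers of top-scoring peaks 0 segments passed in limma, with 70 at an unadjusted p under 0.05, and other random orders of tied scores gave 0 to 12.

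**Figure D4:**
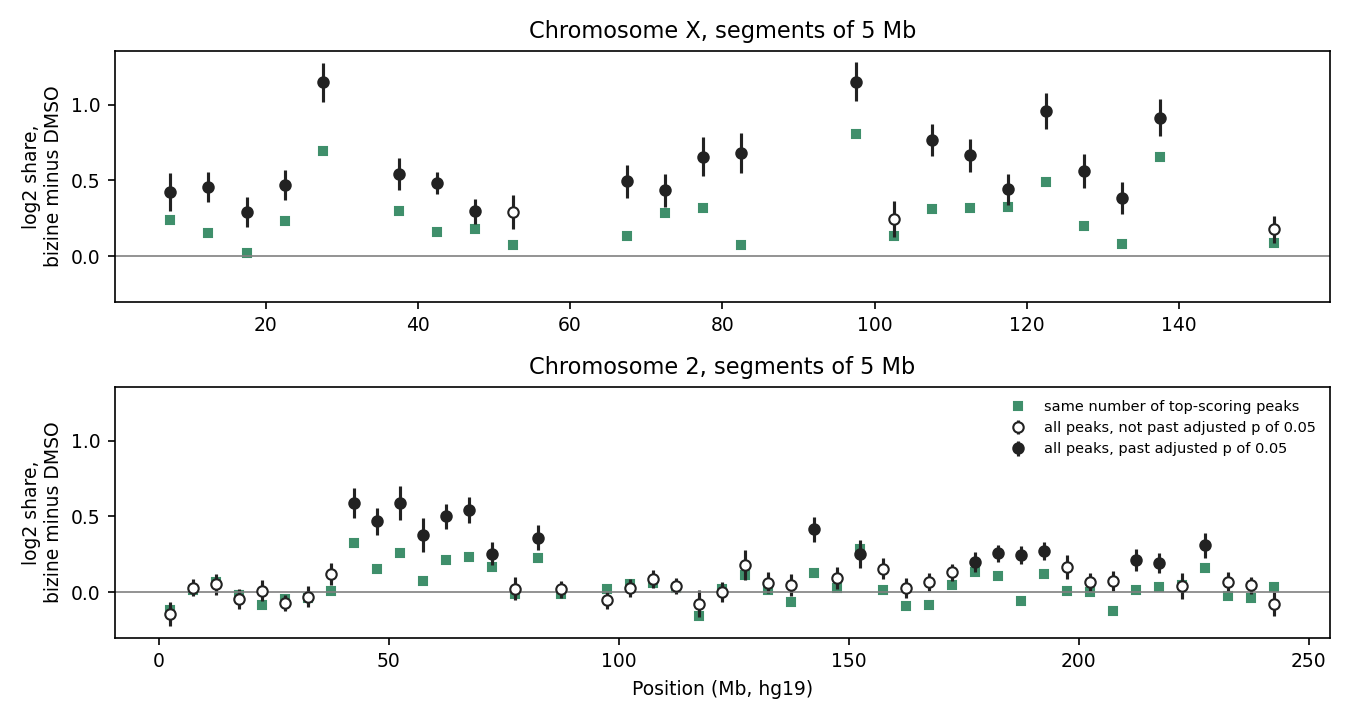
Log2 difference in the share of peaks in 5 Mb segments of chromosomes X and 2 (hg19), libraries labelled bizine minus DMSO. Circles with SE bars use all peaks, filled where the adjusted p was under 0.05, and squares use the same number of top-scoring peaks; 20 of 23 segments on chromosome X and 17 of 48 on chromosome 2 were filled.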

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

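The alternative groups, the order of ties, the shared-region widths, and everything on chromosomes and segments were chosen after seeing the data. So were covered length and mean width with equal numbers of peaks. Mean width and shared-region width kept their direction in all alternatives run, and peak count and covered length in all except groups as the peak names read, which gave -15412 peaks and -2.56 Mb. That grouping also took the shared-region difference from 212 to 3.32 bp and the mean width difference from 76.6 to 39.3 bp, and the latter was 21.0 bp without bizine 1, 132 bp without bizine 2, 158 bp with equal numbers and 121 bp in the top 50%. The 158 bp was raised partly by construction, since the cut drops mainly narrow peaks from the longer lists. Covered length differed by 29.6 Mb, and by 18.0 Mb with equal numbers, where it restates the difference in mean width. By peak names the overlap within minus across groups was -1.97 percentage points, and bins on chromosomes 10, 16, 1 and 19 turned to -13.9, -22.1, -1.16 and 8.14 points and the log2 shares of chromosomes Y and 13 to -0.11 and -0.010, while chromosome X went from 0.53 to 0.0050 (adjusted p = 0.987) and chromosome 2 from 0.12 to 0.0060. Bizine-only regions numbered 6810 with equal numbers of peaks (6807 with ties by width), 7639 with the top 50%, 20692 with 50% presence, 3215 by peak names, and 20481 to 44749 with 1 library left out, which loosens the criterion by construction. DMSO-only regions numbered 3618 (3592 with ties by width), 1193 with joined peaks, 4961 by peak names, and 4422 to 16247 with 1 library left out. Bins passing limma numbered 1015 with the replicate block (1009 higher, 6 lower) and 1 in 10 kb bins, against 0 otherwise. Bin by bin, the deviations of same-numbered libraries were hardly related (r = 0.036). That value cannot show an offset common to all bins, which the block also removes. Covered length was higher in replicate 1 of both groups (74.8 against 61.8 Mb and 102 against 94.0 Mb). Peak count was higher in replicate 1 for DMSO but not for bizine (147397 against 162099). Whether the numbers pair the libraries was thus not decided. Chromosomes numbered 7 with equal numbers (3 with ties by width), 7 with the top 50%, 14 with the replicate block, 0 in both other splits, and 4 to 7 with 1 library left out. Segments numbered 0 with equal numbers (12 with ties by width), 15 with the top 50%, 65 with the replicate block, 0 in both other splits, and 27 to 79 with 1 library left out; a lone library was assumed to vary like the other group. For changes not set by construction, the cause was not tested. Replicate block at bizine-only and DMSO-only regions gives the same sets by construction. Gene windows, gene bodies, gene lists and shares near genes were not run. Depth was unknown, which limits every comparison of counts and widths.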

Other observations

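The counts of one-sided regions and the overlaps with equal numbers of peaks were planned; the bounds set on them and all other tests in this part were chosen after the results had been seen. Groups are those of the labels. Across 553 autosomal segments, which are not independent replicates, the log2 difference in share fell with the segment's median peak score when all peaks were used (Pearson r = -0.566, r = -0.572 without the 2 segments farthest from the median score; permutation p = 1e-05 for the r over all 553 segments, the smallest the resampling can give). Over the 22 autosomes the relation was less clear. With all peaks Pearson's r was -0.404 (permutation p = 0.0734, r = -0.629 without the 2 farthest) and Spearman's rho -0.68 (permutation p = 0.00069). With equal numbers r was 0.638 (permutation p = 0.00978) but 0.0024 without the 2 farthest, on which it rests, and rho 0.299 (permutation p = 0.175). Over all 24 chromosomes with all peaks, rho was -0.756 (permutation p = 4e-05) and r -0.606 (permutation p = 0.00895). Chromosomes Y, X, 13 and 2, whose shares were higher, had the lowest median scores in the DMSO lists (3.50, 3.76, 4.02 and 4.08). Over the 24 chromosomes with equal numbers, rho was -0.0013 (permutation p = 0.996) and r -0.326 (permutation p = 0.114).

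The uneven difference over autosomal segments may reflect segments where weak peaks enter a longer list. Spearman's rho between segment score and difference was -0.60 with all peaks and 0.0012 (permutation p = 0.98) with equal numbers of peaks. The cut by score takes low-scoring peaks out of the longer lists. The weaker relation with equal numbers is thus partly set by construction and does not decide the cause. With equal numbers the log2 difference of chromosome X fell from 0.53 to 0.24 but still passed limma, also in all 10 other orders of tied scores. With smaller equal numbers it did not hold: it was 0.08 among the top 50000, with overlapping groups, and -0.77 among the top 20000. The difference thus changed sign with the cut by score, which does not equalize depth. These values do not tell list length apart from other causes for chromosome X. Chromosome 2 went from 0.12 to 0.032 but still passed limma (adjusted p = 0.037; in 1 of 10 other orders of tied scores), and chromosome Y went from 0.77 to 0.43 without passing (adjusted p = 0.196), so that list length cannot be told apart from other causes for these 2 chromosomes. More copies of chromosome X were not decided by the ranked peaks, since the difference was -0.77 among the 20000 top-scoring peaks, 0.08 among the top 50000 and 0.37 in the top-scoring 50% of each list. List length, copy number, an effect of LSD1 inhibition and a difference in depth stay open, the last 2 untested.

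The larger number of regions in the libraries labelled bizine may come partly from longer lists: with equal numbers the ratio of bizine-only to DMSO-only regions was 1.88, against at most 1.59 in the other 2 splits, which does not decide it. Wider peaks at shared regions were still seen with equal numbers, with a median ratio of 1.20. The cut by score drops mainly weak and narrow peaks from the longer lists and changed the shared set from 60565 to 49993 regions. That ratio therefore does not settle list length. Deeper sequencing could widen peaks at any list length, and without read counts it cannot be set apart from the treatment. List length, depth and treatment thus stay open.

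The peak names could mean that the files of DMSO 2 and bizine 2 were exchanged. With equal numbers of peaks the split by peak name gave 8066 one-sided regions against 10428 by label, and 14.9 and 12.4% of shared regions were wider on 1 side or the other by name, against 33.8 and 7.19% by label. These values argue against an exchange, but the overlaps do not settle it: with all peaks both pairs by label (40.0 and 45.4%) lay above both pairs by name (39.7 and 39.0%), while with equal numbers DMSO 2 overlapped bizine 1, its partner by name, by 40.4% and DMSO 1, its partner by label, by 40.1%. A difference in depth that goes with the labels could also give these values, so the exchange stays open.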
